A study of Sus scrofa domesticus with 6 samples.

How the data were processed

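Bulk RNA sequencing measured gene expression in small intestine of 6 Göttingen minipigs (Sus scrofa domesticus) aged 6 months. Per the labels, 2 animals were unirradiated controls. Another 2 (IR) received 15 Gy of gamma rays from a cobalt source to the abdomen, and 2 more (IR_Pra) received the same exposure and 40 mg of pravastatin by mouth each day for 2 weeks. Tissue was taken on day 14. Each library came from a separate animal, so the numbers 1 and 2 within a group pair nothing. The label of the treated group uses both PS and Pra for the drug, and both were read as pravastatin.

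The deposited table holds 2 values per gene and library. The first is the read count, and the second is FPKM, per the file headers. The count columns were checked to hold whole numbers, and the FPKM columns to follow from the counts and a transcript length. According to the submitters' notes, the authors extracted RNA with Trizol, sequenced it on an Illumina instrument, made reads with bcl2fastq 2.20.0, trimmed them with Trimmomatic (version not given in the sources used here), aligned them with HISAT2 2.1.0 and assembled transcripts with StringTie 2.1.3b. How whole-number counts were made from the assembly is not given in the sources used here. The notes name 2 genome builds, Sscrofa11.1 and GRCh38, and the role of the second is not given there. All 30352 rows with a gene name matched a pig gene of the RefSeq annotation of Sscrofa11.1 by Entrez ID, and coordinates are on that build. Another 24 rows without a gene name held between 0.00906% and 0.0385% of the counts of a library and were left out.

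Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr by group, which left 18197. Scaling used TMM factors. All 6 libraries entered 1 quasi-likelihood fit with a term per group and 3 residual degrees of freedom. The 3 comparisons (IR vs control, IR_Pra vs IR, IR_Pra vs control) were tested with the two-sided quasi-likelihood F test, and p was adjusted by Benjamini-Hochberg over all genes tested within a comparison. The threshold was an adjusted p under 0.05. Values given for a gene are CPM, read counts scaled to library size by the TMM factors,, as mean ± SD over the 2 animals of a group. Log2 fold changes carry a standard error derived from the F statistic. The common biological coefficient of variation was 0.431.

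The 43 gene lists included cholesterol synthesis and SREBP2 targets, p53 and DNA damage response, cell cycle, intestinal stem cell, injured and regenerating epithelium, Paneth and antimicrobial, goblet cell, absorptive enterocyte, brush border enzymes, nutrient transporters, lipid absorption, enteroendocrine, tuft cell, tight and adherens junction, vascular endothelium, endothelial activation and coagulation, extracellular matrix, smooth muscle, enteric neuron and glia, neutrophil, macrophage, T cell, cytotoxic and NK cell, B cell and germinal centre, plasma cell, mast cell and eosinophil, interferon response, antigen presentation, cytokines and chemokines, oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, bile acid and xenobiotic metabolism, unfolded protein response, oxidative stress, immediate early genes, red blood cell, adipose and mesothelium, pancreatic acinar, proximal small bowel, distal small bowel and a list of sex-linked genes. Lists needed at least 5 kept genes, which left 42. They were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 42 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. Camera compares a list with all other genes, so its sign can differ from that of the list's median or mean. For each list the count past the threshold over all genes is given with the count adjusted over the list alone.

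Genes were named by a rule. In each comparison it took, among genes past the threshold with a symbol, separated groups and a mean of at least 1 CPM, the 10 with the highest and the 10 with the lowest log2 fold change. Where fewer than 5 met this in a direction, it took the 5 with the smallest p in that direction and these are said not to have passed. Up to 4 members of a list with the smallest p could be named, and some genes were always named, among them CDKN1A, MDM2, LGR5, OLFM4, MKI67, MUC2, LYZ, THBD, NOS3, COL1A1, IL1B and CXCL8. This rule, the lists, the tests, the threshold and all alternatives except 2 were fixed before the data were examined.

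The alternatives were DESeq2 1.42.0, limma voom, limma trend on log2(FPKM + 1), size factors of DESeq2, library size alone, no filter, a filter of 5 CPM in 2 libraries, robust and legacy edgeR fits, a block for the replicate number, a fit of the 4 libraries of a comparison alone, leaving out each library in turn, other prior counts (0.5 and 5), and other thresholds. The lone library of a group that lost 1 was assumed to vary like the other groups. The 2 alternatives chosen after seeing the data removed the trend with transcript length and kept the rows without a gene name. Transcript length was derived per gene from count, FPKM and library total, and the trend was removed with a lowess curve of span 0.3 per library.

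The genes past the threshold in IR vs control were compared with IR_Pra vs IR. These comparisons share the IR libraries, so 20 simulated data sets per scenario gave the values that shared libraries produce when a gene's spread is the same in every group. A return of 100% places IR_Pra at the control mean.

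Library totals ran from 48600424 to 73975174 counts. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the 2 libraries of the group. Where it had 1 to 3, the ratio of counts is given with its exact 95% interval. Floors and intervals cover counting error only. The gene test was tested on simulated data with 200 changed genes per comparison. It called 0 of 67 genes changed 2-fold in each comparison, between 1 and 8 of 67 changed 4-fold, and between 28 and 44 of 66 changed 8-fold. Between 2 and 9 unchanged genes were also called. The list test called 20 of 20 lists of 20 genes shifted by 1 log2 unit in each comparison with the preset correlation, and between 17 and 20 with the estimated one. It called 0 of the 20 unshifted lists. Genes were drawn independently in these simulations, so they do not measure false calls or power for lists of correlated genes. In the real lists the estimated correlation ran from -0.0694 (injured epithelium) to 0.975 (absorptive enterocyte). Calls were lost in this setting also for lists with an estimate below 0, so correlation among genes cannot account for every loss. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures. GC content was not analysed here, since no genome sequence was at hand.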

Results

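Gene expression was measured by RNA sequencing of small intestine from 6 minipigs, with 2 animals in each of 3 groups: unirradiated control, IR (abdominal irradiation with 15 Gy) and IR_Pra (the same irradiation with 40 mg of oral pravastatin per day for 2 weeks). Pravastatin is a drug that lowers cholesterol synthesis. All tissue was taken on day 14. The control libraries held 57905213 and 62071404 counts, the IR libraries 62165352 and 73975174, and the IR_Pra libraries 48600424 and 51106541. Means below are over n = 2 animals with the SD, and log2 fold changes are followed by their standard error.

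The control and IR_Pra libraries lay close together, and the IR libraries lay apart from them and from each other. Pearson r across 18197 genes, which are not independent replicates, was 0.965 within control, 0.963 within IR_Pra and 0.903 within IR. Between control and IR_Pra libraries it ran from 0.952 to 0.964. Library IR 1 gave 0.901 and 0.908 with the controls, and IR 2 gave 0.847 and 0.863. The IR libraries differed widely in absorptive epithelium: the median of the absorptive enterocyte list, against the control mean, was -0.02 (log2) in IR 1 and -3.95 in IR 2. FABP1, a fatty acid carrier of enterocytes, had a mean of 6185 ± 8591 CPM in IR, against 119.9 ± 40.7 in control and 658.9 ± 330 in IR_Pra. Mitochondrially encoded protein genes took 8.35% and 5.87% of counts in control, 3.91% and 1.48% in IR and 5.31% and 5.90% in IR_Pra. Library IR 1 also showed a trend with transcript length: the tenth of genes with the shortest transcripts had a median log2 ratio to control of 0.65, and the tenth with the longest -0.73. The Spearman correlation with length across genes was -0.37 in IR 1 and between -0.15 and 0.12 in the other libraries.

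**Figure D1:**
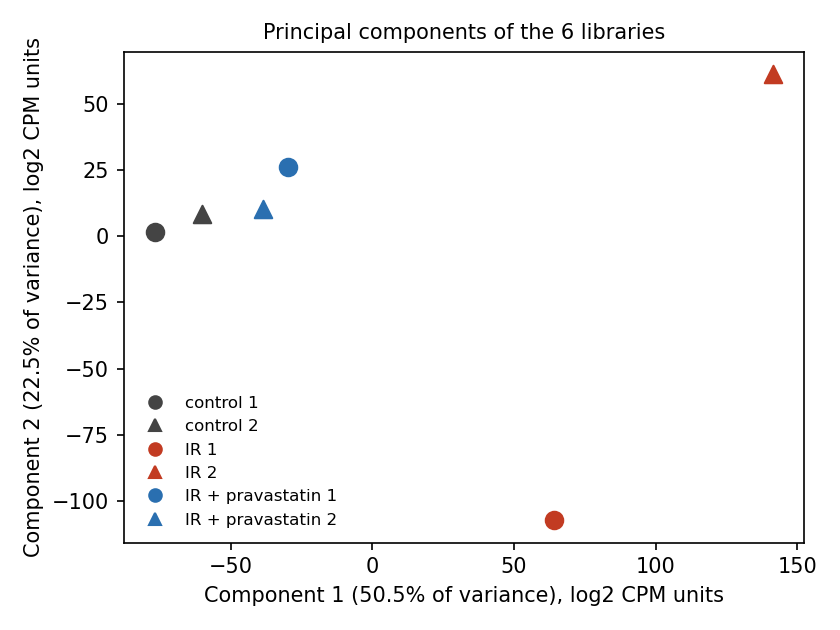
First and second principal components of log2 CPM (50.5% and 22.5% of the variance) for the 6 libraries, coloured by group. Control lies at -76.9 and -60.1 on the first axis, IR_Pra at -29.9 and -38.8, and IR at 64.2 and 142, with the IR libraries at -107 and 61.3 on the second axis.

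The comparison of IR with control asked what abdominal irradiation had changed by day 14. Genes of B cells were among those that fell furthest. PAX5 (Entrez 100520167, chromosome 1, 237574938 to 237785454), the transcription factor that keeps B cell identity, fell from 75.8 ± 3.78 CPM in control to 0.166 ± 0.0286 in IR (log2 fold change -8.83 ± 0.56, adjusted p = 0.0303). GP2 (Entrez 100303610, chromosome 3, 25496533 to 25518210), a receptor for bacteria on the M cells over lymphoid follicles, fell from 131.8 ± 68.8 to 0.149 ± 0.210 CPM (-9.89 ± 1.46, adjusted p = 0.0370). Genes of macrophages were among those that rose furthest, as was 1 gene of the p53 list. TREM2 (Entrez 100737974, chromosome 7, 36465921 to 36471509), a lipid-sensing receptor of macrophages, rose from 0.160 ± 0.178 to 29.1 ± 28.7 CPM (7.47 ± 1.34, adjusted p = 0.0424). PHLDA3 (Entrez 100622793, chromosome 10, 23824181 to 23827428), a p53 target that restrains AKT, rose from 9.21 ± 1.75 to 205 ± 65.4 CPM (4.48 ± 0.36, adjusted p = 0.0331).

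The other genes at the top of the rise were SLC11A1, a metal transporter of the phagosome (6.30 ± 0.67), ASPG (5.28 ± 1.09), CHRDL2 (5.22 ± 0.79), the fast muscle myosin MYH2 (5.09 ± 0.85), the lipid carrier FABP4 (5.04 ± 0.83), S100A2 (4.84 ± 0.28), C1QL4 (4.54 ± 0.53) and the macrophage complement receptor VSIG4 (4.52 ± 0.65), with adjusted p between 0.0243 and 0.0497. S100A2 (Entrez 100152729, chromosome 4, 96073496 to 96076825), a calcium-binding protein of epithelia, rose from 5.45 ± 0.381 to 156 ± 29.5 CPM with the smallest SE of these. FCAMR (Entrez 100522888, chromosome 9, 67585117 to 67601655), a receptor for IgA and IgM, had 6468 counts in control and 3 in IR, a ratio of 2313 with a 95% counting interval of 791 to 11221 (adjusted p = 0.0331). PAEP, P2RY4 and WDR72 had 0 counts in IR and were at least 93.4-fold, 75.5-fold and 71.9-fold lower there. ZP3 (-8.39 ± 1.30), ELL3 (-8.35 ± 0.93) and the complement receptor CR1 (-7.83 ± 0.63) also fell, with adjusted p from 0.0331 to 0.0370. Genes with a higher value in IR had shorter transcripts than genes with a lower one: the median length was 2049 nt for genes that rose, 5206 nt for genes that fell and 3052 nt for all genes with a length.

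Of 18197 genes, 1103 passed the threshold (616 higher and 487 lower in IR), and 5496 had an unadjusted p under 0.05, against 910 by chance. The groups did not overlap for 59.8% of all genes, where chance gives 33.3%, and for all 1103 that passed. Leaving out any library lowers the residual degrees of freedom from which the shared spread is estimated. The count depended on the libraries in that estimate, among them the IR_Pra libraries, which are outside this comparison. It was 5342 without IR 1 and 3284 without IR 2, and it was 0 without either control library and without either IR_Pra library. With library size as the only scaling, 475 genes passed, of which 182 were higher.

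Lymphocyte lists had members that fell. The 20 kept genes of the B cell and germinal centre list had a median log2 fold change of -3.49, with -4.03 in IR 1 and -3.12 in IR 2 against the control mean. Over all genes tested 10 of them passed the threshold and all fell, and 18 fell when adjusted over the list alone (camera adjusted p = 7.28e-10, and adjusted p = 0.600 with an estimated correlation). MS4A1, the B cell surface antigen targeted by rituximab, fell from 41.4 ± 15.1 to 0.181 ± 0.0986 CPM (-7.78 ± 0.69, adjusted p = 0.0345), and FCER2, a low-affinity IgE receptor, fell by 5.13 ± 0.65 (adjusted p = 0.0370). The T cell list had a median of -1.47 over 19 genes, of which 3 fell over all genes and 15 adjusted over the list alone (camera adjusted p = 1.30e-06, and adjusted p = 0.600 with an estimated correlation). CD3D, a chain of the T cell receptor complex, fell from 13.5 ± 1.49 to 3.57 ± 0.710 CPM (-1.92 ± 0.30, adjusted p = 0.0375). Of 16 cytotoxic and NK cell genes, 1 fell over all genes (KLRK1, an activating receptor, -1.63 ± 0.31, adjusted p = 0.0457) and 2 adjusted over the list alone. That list's median was -1.01 (camera adjusted p = 0.00624, 0.104 without IR 2, and adjusted p = 0.600 with an estimated correlation). Plasma cell genes had a median of 0.15 (camera adjusted p = 0.629). Of their 15, TNFRSF17, the receptor for plasma cell survival signals (1.73 ± 0.29), and TXNDC5 (1.44 ± 0.28) rose while FCRL5 (-2.42 ± 0.50) fell, and adjusted over the list alone 5 rose and 2 fell.

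Myeloid and stress-response lists had members that rose. All 18 macrophage genes had a positive log2 fold change, with a median of 2.44, and 10 rose over all genes and 17 adjusted over the list alone (camera adjusted p = 1.73e-09, and adjusted p = 0.593 with an estimated correlation). CD163 (Entrez 397031, chromosome 5, 63300200 to 63334497), the haemoglobin scavenger receptor, rose from 10.1 ± 0.119 to 170 ± 50.7 CPM (4.07 ± 0.30, adjusted p = 0.0331), and C1QA, a subunit of complement C1q, rose by 2.60 ± 0.33 (adjusted p = 0.0370). The neutrophil list had a median of 2.01 over 11 genes. Of these, 3 rose over all genes, among them ALPL (3.03 ± 0.30) and FCGR3A (2.01 ± 0.33), and 6 adjusted over the list alone (camera adjusted p = 0.000869, and adjusted p = 0.593 with an estimated correlation). S100A8, a neutrophil calcium-binding protein, had 2 counts in control and 79 in IR, a ratio of 36.8 with a counting interval of 9.86 to 309. Immediate early genes had a median of 1.32, with 5 of 15 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 0.000869, and adjusted p = 0.593 with an estimated correlation), including FOS (2.96 ± 0.47), JUN (1.40 ± 0.25) and JUNB (1.36 ± 0.24). Fry also called these 3 lists, each with an adjusted p of 0.0359.

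Cytokine and chemokine genes had a median of 0.94. Of 24, 3 rose over all genes, including the chemokines CCL2 (2.35 ± 0.43) and CXCL2 (3.21 ± 0.62), and 9 adjusted over the list alone. Their camera adjusted p was 0.0316, and it was 0.144 without control 2, 0.0690 without IR 2, 0.0557 without IR_Pra 1, 0.330 with a filter of 5 CPM, 0.187 with the length trend removed, and adjusted p = 0.600 with an estimated correlation. IL1B was 0.872 ± 0.334 CPM in control, 1.74 ± 0.458 in IR and 1.16 ± 0.0839 in IR_Pra, and CXCL8 was 19.0 ± 5.54, 16.7 ± 6.69 and 16.9 ± 4.53. The unfolded protein response list had a median of 0.41. Of its 21 genes, 4 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 0.00857, 0.0673 without IR 1, and adjusted p = 0.600 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 6.16 ± 1.97 to 48.5 ± 12.2 CPM (2.98 ± 0.35, adjusted p = 0.0359), and the secretory chaperones CRELD2 and MANF rose by 1.75 ± 0.25 and 1.58 ± 0.26. In the interferon list ISG15 (2.36 ± 0.46) and BST2 (2.55 ± 0.40) rose over all genes, and adjusted over the list alone 3 of 30 rose and 1 fell. That list's median was 0.46 (camera adjusted p = 0.107, 0.0245 without IR 1 and 0.0425 with a filter of 5 CPM). Antigen presentation genes had a median of 0.70 with 0 of 19 past the threshold (camera adjusted p = 0.111, 0.0284 without control 1 and 0.00960 without IR 2), and mast cell and eosinophil genes 0.18 with 0 of 11 (0.787).

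Lists of the muscle wall, nerves and matrix had positive log2 fold changes throughout, and few members passed over all genes. All 16 smooth muscle genes had positive log2 fold changes (median 2.32, with 1.63 in IR 1 and 2.77 in IR 2), and 2 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 1.08e-06, and adjusted p = 0.600 with an estimated correlation). ACTA2, smooth muscle actin, rose from 219.5 ± 24.7 to 639.1 ± 18.8 CPM (1.54 ± 0.27, adjusted p = 0.0413). Enteric neuron and glia genes, all 15 positive, had a median of 1.93, with 4 higher over all genes and 12 adjusted over the list alone (camera adjusted p = 1.08e-06, and adjusted p = 0.600 with an estimated correlation). GFAP, a filament of glia, rose from 2.32 ± 0.247 to 36.2 ± 9.33 CPM (3.97 ± 0.33, adjusted p = 0.0331). Extracellular matrix genes, all 25 positive, had a median of 1.78, with 3 higher over all genes and 16 adjusted over the list alone (camera adjusted p = 7.68e-07, and adjusted p = 0.600 with an estimated correlation). TIMP1, an inhibitor of matrix proteases, rose from 23.6 ± 4.96 to 222 ± 29.6 CPM (3.23 ± 0.28, adjusted p = 0.0331), and the proteoglycan BGN by 2.01 ± 0.29. COL1A1, the main chain of type I collagen, had 510.6 ± 244 CPM in control, 5738 ± 4534 in IR and 1522 ± 285 in IR_Pra (IR vs control 3.49 ± 0.83, adjusted p = 0.0613).

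Vascular endothelium had a median of 0.78 over 18 genes, with 1 higher over all genes (EGFL7, an endothelial growth factor, 1.74 ± 0.26) and 6 adjusted over the list alone. Its camera adjusted p was 0.00364, 0.0561 without control 2, and adjusted p = 0.600 with an estimated correlation. Endothelial activation genes had a median of 0.83 over 19, with 2 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.600 with an estimated correlation). SELE, the selectin that captures leukocytes, rose from 0.109 ± 0.0418 to 1.27 ± 0.668 CPM (3.54 ± 0.70, adjusted p = 0.0472) and the protease ADAMTS1 by 2.44 ± 0.36. THBD, thrombomodulin, had 10.8 ± 3.0 CPM in control, 21.6 ± 2.08 in IR and 12.1 ± 1.39 in IR_Pra, and NOS3, endothelial nitric oxide synthase, 4.48 ± 0.298, 13.8 ± 5.04 and 6.41 ± 0.548. Their adjusted p in IR vs control were 0.0920 and 0.0537.

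**Figure D2:**
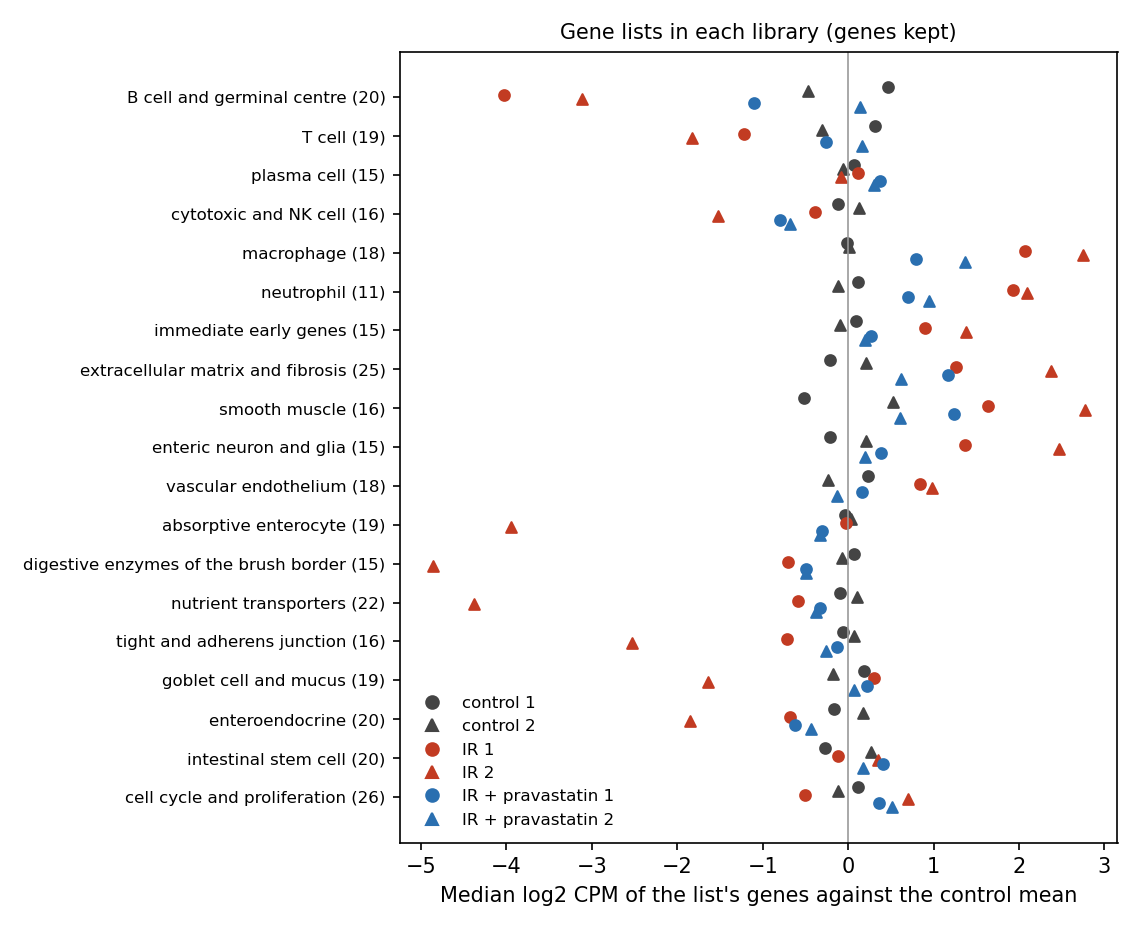
Median log2 CPM of 19 gene lists against the control mean, 1 point per library, with the number of kept genes in brackets. The B cell list lies at -4.03 and -3.12 in IR and at -1.11 and 0.13 in IR_Pra, and the absorptive enterocyte list at -0.02 in IR 1 and -3.95 in IR 2.

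Lists of the absorptive epithelium had few genes past the threshold, and several of their calls depended on IR 2. Tight and adherens junction genes had a median of -1.20 over 16 genes (-0.71 in IR 1 and -2.53 in IR 2), and 1 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000711, and adjusted p = 0.600 with an estimated correlation). F11R, a junctional adhesion molecule, fell from 104 ± 1.71 to 18.4 ± 6.88 CPM (-2.50 ± 0.32, adjusted p = 0.0370). Nutrient transporters had a median of -1.47 over 22 genes. SLC7A8, an amino acid exchanger, fell (-3.05 ± 0.56), SLC46A1, the folate transporter, rose (1.39 ± 0.28), and adjusted over the list alone the counts were the same (camera adjusted p = 0.00845, 0.104 without IR 2, and adjusted p = 0.761 with an estimated correlation). Brush border enzymes had a median of -1.68 over 15 genes, while the 1 that passed over all genes, and adjusted over the list alone, was trehalase (TREH), which rose from 5.25 ± 3.99 to 40.1 ± 0.703 CPM (2.93 ± 0.57, adjusted p = 0.0461). Their camera adjusted p was 0.0316, and it was 0.0614 without control 1, 0.138 without IR 2, 0.0538 with the length trend removed, and adjusted p = 0.761 with an estimated correlation.

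Absorptive enterocyte genes had a median of -0.96, with 0 of 19 past the threshold over all genes or adjusted over the list alone. Their camera adjusted p was 0.0372, 0.0561 without control 2, 0.0538 with the length trend removed, and adjusted p = 0.795 with an estimated correlation, and without IR 2 the direction turned (0.828). Bile acid and xenobiotic genes had a median of -0.74 with 0 of 22 past the threshold in either way. Their camera adjusted p was 0.0423, 0.0561 without control 2, 0.0524 with library size alone, and adjusted p = 0.795 with an estimated correlation, and without IR 2 the direction turned (0.121). Distal small bowel genes had a median of -1.15 with 0 of 11 past the threshold (camera adjusted p = 0.0400, 0.0605 without control 1, 0.828 without IR 2, 0.0509 with the length trend removed, and adjusted p = 0.761 with an estimated correlation). Proximal genes had a median of -0.64 over 10, of which SLC46A1 passed (camera adjusted p = 0.366). Lipid absorption genes had 0 of 22 past the threshold and median, mean and camera that differed in sign (0.07, 0.14 and downward, adjusted p = 0.181, and 4.81e-07 without IR 1). APOA4, a lipoprotein of the chylomicron, was 4470 ± 6305 CPM in IR against 166 ± 71.6 in control, and its log2 fold change was 4.75 ± 2.38 with all libraries and -3.79 without IR 1.

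Secretory and injury-related epithelial genes moved both ways. Enteroendocrine genes had a median of -1.09 over 20 genes, and 3 fell over all genes and 6 adjusted over the list alone. Their camera adjusted p was 0.00624, 0.0690 without IR 2, 0.203 with a filter of 5 CPM, and adjusted p = 0.593 with an estimated correlation. PAX6 (-3.34 ± 0.58) and NEUROD1 (-3.38 ± 0.67), transcription factors of hormone cells, fell, and ghrelin (GHRL) had 0 counts in IR, at least 31.3-fold lower than in control. In the tuft cell list the identity factor POU2F3 (-3.49 ± 0.54) and LRMP (-1.99 ± 0.38) fell over all genes, and adjusted over the list alone 1 of 14 rose and 4 fell (median -0.64, camera adjusted p = 0.168, and 0.0331 without control 1). In the goblet list CREB3L1 rose (1.18 ± 0.22) and ATOH1, the secretory lineage factor (-1.73 ± 0.34), and KLF4 (-2.46 ± 0.50) fell, with the same counts over 19 genes adjusted over the list alone (median -0.33, camera adjusted p = 0.177, and 0.000125 without IR 1). The mucin MUC2 had 4707 ± 1155 CPM in control, 3112 ± 3717 in IR and 4546 ± 397 in IR_Pra.

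Injured and regenerating epithelium had a median of 1.19 over 15 genes, of which 4 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. CYR61, a YAP target (3.50 ± 0.66), and the prostaglandin synthase PTGS2 (1.94 ± 0.32) were among those that rose. The camera adjusted p was 0.0372, 0.0603 without control 2, 0.155 without IR 1, 0.0533 with the length trend removed, and adjusted p = 0.593 with an estimated correlation. Paneth and antimicrobial genes had a median of 1.54 over 13 genes, with 1 higher over all genes and adjusted over the list alone, the iron-sequestering LCN2 (1.76 ± 0.35). Their camera adjusted p was 0.0372, 0.0630 without IR 2, 0.0507 in a fit of 4 libraries, 0.232 with a filter of 5 CPM, 0.0533 with the length trend removed, and adjusted p = 0.593 with an estimated correlation. LYZ, lysozyme, had 216 ± 55.3 CPM in control, 276 ± 225 in IR and 295 ± 69.3 in IR_Pra.

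Of the p53 list, CDKN1A, the inhibitor of the cell cycle (1.29 ± 0.26, adjusted p = 0.0489), PHLDA3 and the nuclease AEN (1.65 ± 0.27) rose over all genes tested, and adjusted over the list alone 5 of 22 rose and 2 fell (median 0.42, camera adjusted p = 0.276). CDKN1A had 74.7 ± 6.04 CPM in control, 182 ± 38.3 in IR and 107 ± 13.8 in IR_Pra, and MDM2 had 13.6 ± 2.78, 15.7 ± 16.1 and 21.4 ± 3.98. Cell cycle genes had 0 of 26 past the threshold over all genes or adjusted over the list alone and a median of 0.17 (camera adjusted p = 0.705), but the IR libraries differed, with -0.50 in IR 1 and 0.70 in IR 2. The list's camera adjusted p was 0.00056 upward without IR 1 and 0.00933 downward without IR 2. MKI67, a marker of dividing cells, had 126 ± 29.0 CPM in control, 105 ± 76.5 in IR and 160 ± 2.57 in IR_Pra. Stem cell genes had a median of 0.31, with 0 of 20 past the threshold over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.383). LGR5, the crypt stem cell receptor, had 2.12 ± 0.795 CPM in control, 0.362 ± 0.197 in IR and 1.41 ± 0.603 in IR_Pra (IR vs control -2.52 ± 0.65, adjusted p = 0.0691), and OLFM4 had 268 ± 100.4, 397 ± 242 and 577 ± 317.

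Lists of cholesterol, energy and redox metabolism did not pass in IR vs control with all 6 libraries. Cholesterol synthesis and SREBP2 targets had a median of 0.69 with 0 of 24 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.239, and 3.43e-05 without IR 2), and the IR libraries lay at 1.36 and -0.57. Oxidative phosphorylation had a median of 0.28 (0 of 19, adjusted p = 0.472, and 0.000645 without IR 2) and glycolysis and hypoxia 0.49 (1 of 22, the vasodilator peptide ADM, 2.04 ± 0.34, list adjusted p = 0.107, and 0.00198 without IR 2). In the fatty acid oxidation list 2 of 19 genes fell over all genes and adjusted over the list alone, among them PPARA, the receptor that drives this pathway (-3.39 ± 0.40), and median, mean and camera differed in sign (0.05, 0.43 and downward, adjusted p = 0.592, and 0.0432 without control 1). Oxidative stress genes had 0 of 16 past the threshold, with median and mean (-0.13 and -0.03) against an upward camera sign (adjusted p = 0.936).

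Markers of other tissues were measured beside these. Red blood cell genes had a median of 2.63, or 2.30 with AHSP at its bound (0 of 6, adjusted p = 0.199, and 0.0452 with a replicate block). Adipose and mesothelium genes had 0.87 (1 of 8, FABP4, and 3 adjusted over the list alone, adjusted p = 0.306). Pancreatic acinar genes had a median of 0.24, a mean of 0.40 and a downward camera sign (0 of 6, adjusted p = 0.936). Of the sex-linked list only 1 gene was kept, so it was not tested. In all, camera called 22 of 42 lists (12 up and 10 down), 0 with an estimated correlation (smallest adjusted p = 0.593) and 3 by fry. Other medians of lists with a gene at 0 in a group did not move with that gene at its bound.

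**Figure D3:**
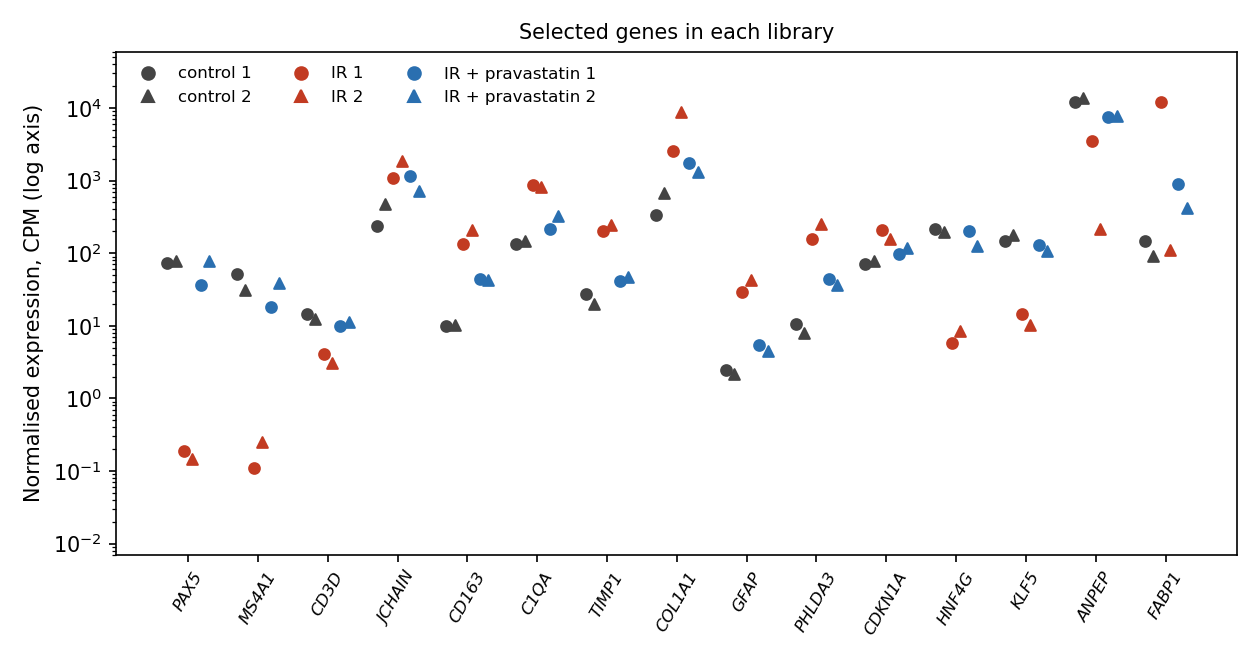
Normalised expression (CPM, log axis) of 15 genes, 1 point per library, with colours for the 3 groups and circles and triangles for libraries 1 and 2. PAX5 lies at a mean of 75.8 in control, 0.166 in IR and 57.1 in IR_Pra, and CD163 at 10.1, 170 and 43.3.

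The comparison of IR_Pra with IR asked what pravastatin changed in irradiated intestine. Only 1 gene passed the threshold. It is LOC110255225 (Entrez 110255225, 3717842 to 3723115 on sequence not placed on a chromosome), which lacks a symbol and was chosen after its values were seen. The annotation lists it as a constant region segment of an immunoglobulin or T cell receptor. It had 51.9 ± 10.8 CPM in control, 0 counts in IR and 66.6 ± 5.47 CPM in IR_Pra, so it was at least 2877-fold higher in IR_Pra than in IR (adjusted p = 0.0339), and at least 2241-fold lower in IR than in control (adjusted p = 0.0243). Constant region segments with nearby coordinates had 0 counts in single libraries of any group: LOC110258346 in the second library of each group and LOC110258349 in IR 2. The coordinates of LOC110255225 lie within those given for the constant region LOC102165485 (3580107 to 3774450, also unplaced). That gene went the other way, with 2796 ± 99.7 CPM in control, 15469 ± 2214 in IR and 5409 ± 107 in IR_Pra. Whether inherited differences between the animals at this locus, or reads counted to the other gene, give the values of LOC110255225 was not tested. As groups, with a preset correlation, B and T cell genes were higher with pravastatin, and macrophage, neutrophil and nerve genes were lower. Over all genes 0 members of these lists passed by edgeR, and every one of these calls was lost with an estimated correlation (adjusted p = 0.942 with an estimated correlation). Immediate early genes, with an estimated correlation of -0.00663, lost their call as well. A lost call thus does not by itself show that the genes of a list are correlated.

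The B cell list had a median of 2.93 in IR_Pra vs IR, with 0 of 20 past the threshold over all genes and 17 higher adjusted over the list alone (camera adjusted p = 3.82e-10). The T cell list had a median of 1.48, with 0 of 19 over all genes and 14 higher adjusted over the list alone (camera adjusted p = 4.33e-07). Macrophage genes had a median of -1.22 (0 of 18 over all genes, 5 lower adjusted over the list alone, camera adjusted p = 4.64e-05). Neutrophil genes had -1.41 (0 of 11, 4 lower adjusted over the list alone, 0.00977), and immediate early genes -0.96 (0 of 15, 6 lower adjusted over the list alone, 0.00344). Enteric neuron and glia genes had -1.34 (0 of 15, 7 lower adjusted over the list alone, 4.29e-06), and vascular endothelium -0.74 (0 of 18, 5 lower adjusted over the list alone, 0.00344). Each of these 7 calls was lost with an estimated correlation (adjusted p = 0.942 with an estimated correlation), and each stayed past the threshold without any single library.

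A second set of lists depended on IR 2, the library with low enterocyte values. Junction genes had a median of 1.0 (0 of 16 over all genes, 3 higher adjusted over the list alone, camera adjusted p = 0.00157, and 0.269 without IR 2). Brush border enzymes had 0.99 (0 of 15 in either way, 0.0128, and 0.634 without IR 2) and transporters 0.92 (0 of 22 in either way, 0.0173, and 0.800 without IR 2). Extracellular matrix genes had -0.92 (0 of 25 over all genes, 1 lower adjusted over the list alone, 0.00157, and 0.247 without IR 2), and smooth muscle -1.50 (0 of 16 in either way, 0.00068, and 0.0952 without IR 2). Distal small bowel genes had 0.36 (0 of 11, 0.0231), with 0.0511 in a fit of 4 libraries, 0.0694 with a filter of 5 CPM and 0.0844 without IR_Pra 1, and the direction turned without IR 2 (0.800). These 6 calls were lost with an estimated correlation too (adjusted p = 0.942).

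The genes with the smallest p did not pass. PAX5 had 57.1 ± 29.8 CPM in IR_Pra (8.43 ± 0.55, adjusted p = 0.0548) and CR1 75.6 ± 36.3 (7.78 ± 0.62, adjusted p = 0.0612). HNF4G (Entrez 110260272, chromosome 4, 60505388 to 60641052), a nuclear receptor of enterocytes, had 203 ± 13.9 CPM in control, 7.15 ± 2.0 in IR and 162 ± 53.3 in IR_Pra (4.50 ± 0.38, adjusted p = 0.0612). KLF5 (Entrez 100038005, chromosome 11, 45370009 to 45386673), a crypt transcription factor, had 162 ± 21.2, 12.4 ± 3.03 and 119 ± 16 CPM (3.27 ± 0.30, adjusted p = 0.0612). FCAMR had 3 counts in IR and 4840 in IR_Pra, a ratio of 1989 with a counting interval of 680 to 9647. On the lower side, with an adjusted p of 0.0754, were GFAP (-2.86 ± 0.32), S100A2 (-2.12 ± 0.24), TIMP1 (-2.32 ± 0.27), TSSC4 (-1.97 ± 0.23) and the DNA repair enzyme MGMT (-2.20 ± 0.26).

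Genes fixed in advance for radiation injury had values without a call. COL1A1 was at -1.91 ± 0.78, NOS3 at -1.11 ± 0.35, THBD at -0.83 ± 0.30 and CDKN1A at -0.77 ± 0.26. LGR5 was at 1.93 ± 0.64 and the rest lay between -0.58 (IL1B) and 0.61 (MKI67), with adjusted p from 0.134 to 0.980. Cholesterol synthesis had a median of -0.39 (0 of 24, camera adjusted p = 0.634). It was past the threshold downward without IR 2 (adjusted p = 0.000200) and upward without IR 1 (0.0222). Endothelial activation had -0.46 (0.227), injured epithelium -0.89 (0.227), p53 -0.09 (0.634, with 1 higher and 2 lower adjusted over the list alone), cell cycle 0.27 (0.143, 5.74e-06 without IR 2, 0.0461 without IR_Pra 1 and 0.0416 with the length trend removed) and stem cell 0.09 (0.740).

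Among the epithelial lists, goblet had a median of 0.55 (adjusted p = 0.0656, 5.10e-06 without IR 1, 0.0242 with a replicate block and 0.0385 with no filter), absorptive enterocyte 0.62 (0.050, not past the threshold), Paneth -0.20 (0.956, 1 lower adjusted over the list alone), enteroendocrine 0.30 (0.0973, 3 higher and 1 lower), tuft 0.37 (0.333, 2 higher), proximal 0.07 (0.738, 1 lower) and bile acid 0.03 (0.168). Enteroendocrine genes passed without IR 1 (0.0226), without IR_Pra 1 (0.0350) and with the length trend removed (0.0205), and bile acid genes passed upward without IR 1 (1.12e-08) and downward without IR 2 (0.0104). The absorptive enterocyte list passed without IR 1 (1.99e-12), control 1 (0.0396), control 2 (0.0403) or IR_Pra 1 (0.0461). It also passed with a replicate block (0.0221), no filter (0.0276), a filter of 5 CPM (0.0439), a prior count of 5 (0.0445) and in a fit of 4 libraries (0.0411). Its adjusted p was 0.942 with an estimated correlation, and without IR 2 it was 0.119 with a downward sign. Lipid absorption had a median of -0.17 and a mean of -0.30 against an upward camera sign (0.296), and passed upward without IR 1 (1.01e-07) and downward without IR 2 (0.0149). Among immune lists, cytotoxic cells had 0.02 (0.526, and 0.0172 without IR 1), plasma cells 0.18 (0.726, 1 higher adjusted over the list alone), mast cells -0.38 (0.738), interferon -0.10 (0.672), antigen presentation -0.39 (0.461, and 0.0434 without IR_Pra 2) and cytokines -0.41 (0.302). Oxidative phosphorylation had -0.16 (0.683, downward at 0.00144 without IR 2 and upward at 0.0246 without IR 1), glycolysis -0.43 (0.155, and 0.00357 without IR 2), unfolded protein response -0.25 (0.143), red blood cell -0.49 (0.744) and adipose -0.54 (0.683). Fatty acid oxidation (median -0.25, mean -0.20, 2 higher adjusted over the list alone, 0.683, and 0.0321 without IR 1) and pancreatic acinar genes (-0.40, -0.37, 0.946) had an upward camera sign, as did oxidative stress genes (median -0.03, mean 0.35, 0.672). Where no count is given, 0 members passed over all genes or adjusted over the list alone.

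Of 18197 genes 1 passed by edgeR, 4467 had an unadjusted p under 0.05, 2543 passed by DESeq2 and 0 by limma voom. The count was 3728 without IR 1, 2317 without IR 2 and 0 without either control or either IR_Pra library. The groups did not overlap for 53.9% of genes, where chance gives 33.3%. Camera called 13 of 42 lists (6 up and 7 down), and 22 without IR 1. With library size alone as the scaling, the median of all genes was 0.14, against -0.02 with TMM.

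The comparison of IR_Pra with control asked what still differed from unirradiated intestine under pravastatin. By edgeR 0 genes passed the threshold, while DESeq2 called 65 (50 higher and 15 lower) and limma voom 0. An unadjusted p under 0.05 was reached by 623 genes (436 higher and 187 lower), against 910 by chance. That fit shares its spread with the IR libraries. In an edgeR fit of the 4 control and IR_Pra libraries alone, 1668 of 17617 genes reached it and 0 passed (smallest adjusted p = 0.102). As groups, macrophage, matrix and smooth muscle genes were higher than in control. All 18 macrophage genes had positive log2 fold changes with a median of 1.18, and 5 rose adjusted over the list alone (0 over all genes, camera adjusted p = 2.20e-12, and adjusted p = 0.347 with an estimated correlation). CD163 had 43.3 ± 1.13 CPM against 10.1 ± 0.119 in control (2.1 ± 0.28, adjusted p = 0.823). Extracellular matrix had a median of 0.91 (camera adjusted p = 4.47e-08, and adjusted p = 0.506 with an estimated correlation) and smooth muscle 0.93 (camera adjusted p = 2.62e-07, and adjusted p = 0.482 with an estimated correlation). Endothelial activation had 0.49 (camera adjusted p = 1.07e-05, and adjusted p = 0.347 with an estimated correlation), Paneth genes 1.04 (0.000209, 1 higher adjusted over the list alone, and adjusted p = 0.347 with an estimated correlation) and cytotoxic and NK cell genes -0.81 (7.02e-06, and adjusted p = 0.347 with an estimated correlation). These 6 lists stayed past the threshold without any single library.

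The other 14 called lists each lost the call without at least 1 library. Cell cycle had a median of 0.44 (camera adjusted p = 0.000283, 0.0861 without control 2, 0.0516 without IR_Pra 2, and adjusted p = 0.931 with an estimated correlation), with 25 of 26 genes positive. Stem cell genes had 0.33 (0.0140, 0.646 without control 1, 0.399 without IR_Pra 1, and adjusted p = 0.931 with an estimated correlation). Injured epithelium had 0.73 (0.00656, 0.0556 without IR_Pra 2, and adjusted p = 0.347 with an estimated correlation) and enteroendocrine genes -0.59 (0.00134, 0.0988 without control 2, and adjusted p = 0.347 with an estimated correlation). Neutrophil genes had 1.02 (0.00134, 0.111 without control 2, 0.112 in a fit of 4 libraries, 1 higher adjusted over the list alone, and adjusted p = 0.347 with an estimated correlation). B cell genes had -0.41 (0.0279, 0.0771 without IR 1, 0.0732 without IR 2, 0.0677 in a fit of 4 libraries, and adjusted p = 0.947 with an estimated correlation), and the direction turned without control 1 (0.773) and without IR_Pra 1 (0.267). Plasma cell genes had 0.31 (0.0140, 0.256 without control 2, 0.0971 without IR_Pra 2, and adjusted p = 0.347 with an estimated correlation). Interferon genes had 0.33 (0.0117, 0.0536 without control 1, 0.711 without IR_Pra 2, and adjusted p = 0.724 with an estimated correlation).

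Cytokines had 0.33 (0.00134, 0.394 without control 2, 0.0611 without IR_Pra 2, and adjusted p = 0.439 with an estimated correlation) and unfolded protein genes 0.20 (0.00149, 0.111 without control 2, and adjusted p = 0.439 with an estimated correlation). Enteric neuron and glia genes had 0.28 (0.0386, 0.547 without control 1, 0.239 without IR_Pra 1, 0.0516 without IR_Pra 2, 0.0578 with library size alone, and adjusted p = 0.943 with an estimated correlation). Immediate early genes had 0.26 (0.0386, 0.402 without control 2, 0.0709 without IR 1, 0.0679 without IR 2, 0.239 without IR_Pra 1, 0.0660 in a fit of 4 libraries, 0.0507 with the length trend removed, and adjusted p = 0.356 with an estimated correlation). Red blood cell genes had a median of 2.00, or 1.92 with AHSP at its bound (0.0390, 0.0748 without control 1, 0.237 without IR 1, 0.525 without IR 2, 0.139 without IR_Pra 2, 0.513 in a fit of 4 libraries, 0.0578 with library size alone, 0.0715 with the length trend removed, 0.0588 with a prior count of 5, and adjusted p = 0.436 with an estimated correlation). Adipose and mesothelium genes had 0.52 (0.0140, 0.0898 without control 1, 0.353 without IR_Pra 2, 0.231 in a fit of 4 libraries, 0.0721 with no filter, and adjusted p = 0.356 with an estimated correlation). Over all genes 0 members of any list passed, and adjusted over the list alone members passed in the macrophage, Paneth, neutrophil, p53 and oxidative stress lists and in 0 of the others.

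T cell genes had a median of 0.03 (camera adjusted p = 0.999), enterocyte -0.28 (0.657), transporters -0.39 (0.309), junction -0.19 (0.171), lipid absorption -0.30 (0.576), bile acid -0.24 (0.246), goblet 0.08 (0.50), tuft -0.17 (0.207, 0.0334 without control 1 and 0.0437 without IR_Pra 2), cholesterol synthesis 0.26 (0.225, and 0.0334 without control 1) and p53 0.03 (0.130, 1 higher adjusted over the list alone). Antigen presentation had 0.18 (0.0811, 0.00431 without control 1, 0.000115 without IR_Pra 1 and 0.0334 with a filter of 5 CPM), oxidative phosphorylation 0.04 (0.697), proximal genes -0.65 (0.445), distal genes 0.05 (0.920) and oxidative stress 0.20 (0.334, 1 higher adjusted over the list alone, the glutathione peroxidase GPX2, and 0.0396 without IR_Pra 1). Without IR 1, without IR 2 and in a fit of 4 libraries, enterocyte genes (adjusted p = 0.0163 to 0.0179), junction genes (0.0163 to 0.0179), transporters (0.000725 to 0.000988) and brush border enzymes (0.0163 to 0.0179) passed and lay lower in IR_Pra. Median, mean and camera differed in sign for brush border enzymes (-0.40, 0.01, upward, adjusted p = 0.920), vascular endothelium (-0.02, 0.03, upward, 0.920, and 0.0334 without control 1), mast cells (-0.20, 0.55, downward, 0.920), glycolysis (-0.01, 0.07, upward, 0.517), fatty acid oxidation (-0.20, 0.22, downward, 0.657, and 0.0102 without control 1) and pancreatic acinar genes (0.05, 0.03, downward, 0.998).

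The genes with the smallest p, which did not pass, were S100A2, with 35.8 ± 1.94 CPM against 5.45 ± 0.381 in control (2.71 ± 0.25, adjusted p = 0.255), and HOXA9 (Entrez 100519066, chromosome 18, 45404594 to 45411512), a regional patterning factor, with 26.9 ± 17.3 CPM against 0.191 ± 0.0234 (7.12 ± 0.71, adjusted p = 0.296). TREX2 (2.83 ± 0.36), CD163 and KIF12 (2.12 ± 0.31) followed on the higher side. On the lower side were HAUS7 (-2.79 ± 0.44), FAM229A (-1.47 ± 0.24), the clock output factor DBP (-1.38 ± 0.25), KCNJ3 (-2.50 ± 0.46) and RIMBP2 (-2.22 ± 0.48). COL1A1 was at 1.58 ± 0.77, OLFM4 at 1.11 ± 0.61, CDKN1A at 0.51 ± 0.26 and NOS3 at 0.52 ± 0.35, and the other genes always named lay between -0.59 (LGR5) and 0.65 (MDM2). The groups did not overlap for 40.8% of genes, where chance gives 33.3%. Camera called 20 of 42 lists (17 up and 3 down), and 13 without control 2 or without IR_Pra 2.

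Genes changed by irradiation lay near their control level in the pravastatin group. Of the 1103 genes past the threshold in IR vs control, 1102 had the opposite sign in IR_Pra vs IR, and 1005 (91.1%) lay nearer to control than to IR. The median return was 80.7%, with quartiles of 66.7% and 91.9%. PAX5 went from 75.8 to 0.166 and to 57.1 CPM, KLF5 from 162 to 12.4 and to 119, and TIMP1 from 23.6 to 222 and to 44.3. PHLDA3 lay at 40.2 ± 5.28 CPM in IR_Pra against 9.21 ± 1.75 in control and 205 ± 65.4 in IR. By edgeR 1 gene, LOC110255225, passed both thresholds in opposite directions. Independent lists would share 0.0268, but these lists share the IR libraries. As edgeR called 0 genes in IR_Pra vs control, 0 could pass in the same direction there. DESeq2 gave 2185 opposite calls and 49 in the same direction in IR_Pra vs control. The opposite calls of edgeR were 3476 without IR 1, 1977 without IR 2 and 0 without any 1 of the other 4 libraries.

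Because both comparisons share the IR libraries, part of this follows from their spread. Over the 1000 genes with the smallest p the median return was 80.9%. Simulated data with no effect in any group gave 49.6% (46.4% to 52.9% over 20 draws). All simulations gave each gene the same spread in every group. The real IR libraries differed more from each other (Pearson r 0.903) than the control (0.965) or IR_Pra libraries (0.963). A wider spread in IR alone raises the return without any effect. The simulations without effect therefore cannot tell how much of the observed return such a spread gave. Simulations with IR_Pra drawn from the control means gave a median return of 91.9% (90.3% to 93.9%). Midway on the log scale it was 50.3% (49.2% to 51.6%), and from the IR means 7.98% (5.97% to 9.42%). On average 3117, 3074 and 3034.5 genes passed in IR vs control in these scenarios, against 1103 in the data. Opposite calls averaged 2164 (2032 to 2328) from the control means, 21.15 midway and 0.25 from the IR means, against 1 in the data. These scenarios called more genes in IR vs control than the data did, so their returns alone cannot place IR_Pra between control and IR. The sign in IR_Pra vs IR was opposite for 100% of the 1000 genes, and for 87.2% (85.4% to 89.2%) in the simulations without effect. The share with the same sign in IR_Pra vs control was 89.8%. It was 87.1% (83.5% to 88.6%) in the simulations without effect, 66.6% with IR_Pra drawn from the control means, 99.1% midway and 99.8% from the IR means. Pearson r across genes, which are not independent replicates, between the log2 fold changes of IR vs control and IR_Pra vs IR was -0.83. It was -0.50 in the simulations without effect, where the same limit of an equal spread in every group holds.

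**Figure D4:**
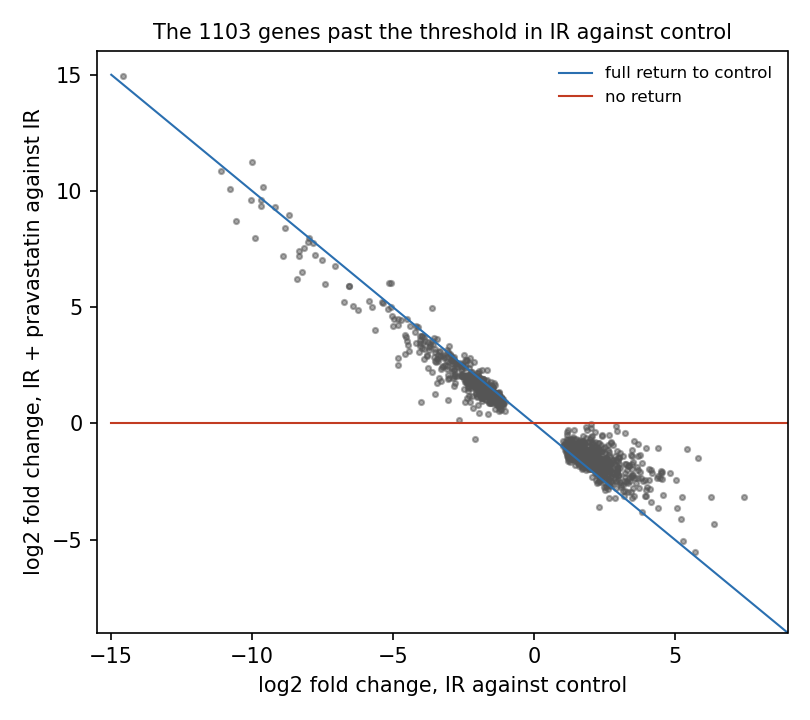
Log2 fold change of IR vs control (horizontal) and of IR_Pra vs IR (vertical) for the 1103 genes past the threshold in IR vs control, with lines for a full return to control and for no return, where points of genes at 0 counts in IR depend on the prior count. All but 1 of the points lie on the side of return, with a median return of 80.7%.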

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

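Removing the length trend and keeping the rows without a gene name were chosen after the results were seen, and the other alternatives were planned. In IR vs control 1103 genes passed, and the direction of these genes was the same under every alternative that gave them a value. The groups did not overlap for any of the 1103, so leaving out a library could hardly turn a direction. The unchanged direction is therefore no independent support. The count was 475 with library size only, 3828 with DESeq2, 403 with limma trend on FPKM, 3452 at an adjusted p under 0.10, 4235 at an unadjusted p under 0.05 with a log2 size of at least 1, 0 with a replicate block and 0 in a fit of 4 libraries only. Leaving out 1 library gave 0 to 5342: 0 without control 1, control 2, IR_Pra 1 or IR_Pra 2, 5342 without IR 1 and 3284 without IR 2. Under the remaining alternatives it was 790 to 1249, with 979 after removal of the length trend, 719 of them among the 1103. Leaving out any library also lowers the residual degrees of freedom of the shared spread. This loss is the same for each library, so it cannot give a rise without an IR library beside a fall without another. How far it gave the falls was not tested. Of the 83 named genes that passed, 57 still did with the length trend removed, 64 with limma voom and 83 with DESeq2.

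In IR_Pra vs IR 1 gene passed, with 2 for library size only, 2 without a filter, 0 with a replicate block, 0 in 4 libraries only, 2543 with DESeq2, 0 with limma voom, 1328 at an adjusted p under 0.10, 3153 at an unadjusted p under 0.05 with a log2 size of at least 1, and 0 to 3728 leaving out 1 library (3728 without IR 1, 2317 without IR 2 and 0 without any 1 of the other 4). In IR_Pra vs control 0 genes passed by edgeR, with 65 by DESeq2, 0 by limma voom and 462 at an unadjusted p under 0.05 with a log2 size of at least 1. Genes past both thresholds in opposite directions (1) were 2185 with DESeq2, 0 with a replicate block, 2 with library size only, 1241 at an adjusted p under 0.10, and 0 to 3476 leaving out 1 library (3476 without IR 1, 1977 without IR 2 and 0 without any 1 of the other 4). The cause was not tested.

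Lists past the threshold in IR vs control (22) were 0 with an estimated correlation, 3 by fry and 17 to 24 leaving out 1 library. In IR_Pra vs IR (13) they were 0 with an estimated correlation, 0 by fry and 13 to 22 leaving out 1 library (22 without IR 1). In IR_Pra vs control (20) they were 0 with an estimated correlation, 0 by fry and 13 to 21 leaving out 1 library (13 without control 2 or IR_Pra 2). The cause of these changes was not tested.

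Some list directions turned with the threshold passed before or after the turn, and turns of lists past it in neither are left out here. Ranges are of the camera adjusted p leaving out 1 library. In IR vs control these were absorptive enterocyte (8.42e-10 to 0.828, turned without IR 2), bile acid and xenobiotic metabolism (1.85e-08 to 0.121, turned without IR 2) and cell cycle (0.00056 to 0.859, turned at 0.00933 without IR 2). In IR_Pra vs IR these were bile acid (1.12e-08 to 0.285, turned at 0.0104 without IR 2), cholesterol synthesis (0.000200 to 0.797, turned at 0.0222 without IR 1), distal small bowel (1.47e-07 to 0.800, turned without IR 2), lipid absorption (1.01e-07 to 0.393, turned at 0.0149 without IR 2) and oxidative phosphorylation (0.00144 to 0.774, turned at 0.0246 without IR 1). In IR_Pra vs control these were B cell (2.54e-07 to 0.773, turned without control 1 and at 0.267 without IR_Pra 1) and brush border enzymes (0.0178 to 0.991, turned at 0.0178 without IR 1, 0.0179 without IR 2 and 0.0163 in a fit of 4 libraries only). By the same rule, log2 fold changes turned for APOA4 (-3.79 to 5.75), APOC3 (-1.85 to 7.21) and MDM2 (-1.66 to 0.99) in IR vs control, and for APOA4 (-5.72 to 4.32), APOC3 (-5.44 to 3.62) and FABP1 (-4.22 to 2.59) in IR_Pra vs IR. MDM2 turned without IR 2 and the other genes without IR 1. The cause was not tested. With 2 animals per group, the test recovered 0 of 67 simulated genes changed 2-fold. Depth limits the genes near the floor of 3 counts, whose folds are lower bounds or carry a counting interval.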

Other observations

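The values on immunoglobulin segments and on HOX genes, and the tests on the length trend, on the muscle and nerve lists and on plasma cells, were chosen after the results were seen. Genes annotated as variable segments of immunoglobulins or T cell receptors carry the antigen-binding part. Of 66 kept variable segments, 13 rose and 0 fell past the threshold in IR vs control, and 34 of the 66 had a positive log2 fold change. LOC110258687 had 7.14 ± 0.648 CPM in control, 55.8 ± 8.46 in IR and 24.8 ± 8.66 in IR_Pra (log2 fold change 2.97 ± 0.33, adjusted p = 0.0359), and LOC110258328 rose by 4.21 ± 0.61 (adjusted p = 0.0370). Of 13 constant regions, 2 rose, LOC110256717 (1.67 ± 0.29, adjusted p = 0.0413) and LOC102158332 (1.62 ± 0.33, adjusted p = 0.0485), both on chromosome 14. Another 2 fell, LOC110255225 and LOC110258348 (-4.82 ± 0.75, adjusted p = 0.0371). The constant region with most counts, LOC102165485, had 2796 ± 99.7 CPM in control, 15469 ± 2214 in IR and 5409 ± 107 in IR_Pra (2.47 ± 0.76, adjusted p = 0.0977). Some segments were at 0 in part of the libraries: 6 of 13 constant regions and 24 of 66 variable segments had 0 counts in at least 1 library, and LOC110258346 had 0 counts in the second library of every group. These genes were not fitted under the alternatives of the processing one by one.

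Homeobox genes, which pattern the body axis, had values in the pravastatin group that did not pass a threshold. HOXA9 had 0.191 ± 0.0234 CPM in control, 0.583 ± 0.227 in IR and 39.2 and 14.7 in the 2 IR_Pra libraries. HOXB6 had 17.9 ± 4.35, 38.4 ± 18.7 and 134 ± 48.9 CPM (IR_Pra vs control 2.90, adjusted p = 1), and HOXA10 had 0 counts in control and IR and was at least 26.7-fold higher than control in IR_Pra. HOXA5, HOXA6, HOXB7 and HOXC10 also had their highest group mean in IR_Pra. Others did not share this, such as HOXC5 with 1.42 ± 0.0769, 5.85 ± 2.31 and 0.984 ± 0.384 CPM. The site of sampling is not given beyond small intestine. A difference of site between the groups therefore cannot be told apart from an effect of treatment in the comparisons with IR_Pra. In IR vs control HOXB5 rose by 1.99 (adjusted p = 0.0454), the only 1 of the 24 HOX genes given here to pass.

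The absorptive enterocyte list was far lower in IR 2 (median -3.95 against the control mean) than in IR 1 (-0.02). The trend with transcript length is argued against, since the median was -4.01 with the trend removed. A smaller share of epithelium in that piece cannot be told apart from a change within it: the pan-epithelial list of 16 genes had a median of -1.92 ± 0.21 (SE over genes), within its error of the bound set in advance. A piece from the large bowel stays open as well, as 4 of the 6 list genes of posterior HOX and colon were already abundant in control (median -3.31 ± 1.52). The irradiation itself, with a different course in each animal, was not tested.

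All kept smooth muscle, nerve and matrix genes had positive log2 fold changes in IR vs control, and the 3 list calls were lost with an estimated correlation (adjusted p = 0.600). The length trend as the whole cause is argued against, since with it removed and the correlation preset the largest adjusted p of the 3 lists was 2.35e-06. A larger share of muscle wall in the irradiated pieces is a candidate explanation and needs smooth muscle and nerve medians that rise alike. They differed by 0.30 ± 0.31 in IR 2 and 0.26 ± 0.33 in IR 1 (SE over genes, which are not independent replicates). With errors this wide, these values do not tell this explanation from others. Fibrosis or remodelling after irradiation was not tested against it.

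The B cell list was lower in IR (median -3.56 against the control mean). Plasma cell genes, which dilution by other tissue would lower too, had a median of 0.0196 ± 0.34 (SE over genes). This argues against dilution as the whole cause only if plasma cells did not increase. Such an increase was not tested, and some plasma cell and immunoglobulin genes rose in IR. Whether the irradiated pieces held fewer lymphoid follicles, or follicles without B cells, cannot be told apart, since the 5 follicle stroma genes had a median of 0.25 ± 1.27 with members going both ways. A loss of radiosensitive B cells may underlie these values and was not tested apart from these.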
